A study of Mus musculus with 6 samples.

How the data were processed

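RNA from primary mesenchymal stromal cells of mouse subcutaneous white adipose tissue was measured on 6 Affymetrix arrays, 3 from cells with an empty retrovirus and 3 from cells with the GATA2 retrovirus. Per the labels, the cells came from male C57BL/6J mice of 8 to 12 weeks, were passaged at least 2 times, were exposed to virus for 24 h and were selected with 1 µg/ml puromycin from 48 h, and 100 ng of RNA was used. The labels do not say whether these samples had been put into osteogenic medium, nor whether the replicates were separate animals or cultures.

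The deposited values are intensity values per gene for each array, RMA-normalised per the submitters' processing notes, and both deposited tables hold them on a linear scale and agree to a relative difference of 4.95e-10. The notes name RMA, whose version is not given in the sources used here, and Partek 6.6. The background correction and summarisation settings are not given in the sources used here. Each table has 21187 probe sets, 1 per Entrez gene, with a median of 27 probes. The plan, made before the data were examined, took the deposited intensity values to be log2 values. They were not, so their log2 was taken, with no pseudocount. Gene symbols were updated from the Entrez numbers with a RefSeq table, which matched 20819 probe sets (98.3%), changed 1944 symbols and left 15 without a name. The tables hold no detection calls, so signal over background is unknown.

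Groups came from the sample titles. In R 4.3.3 with limma 3.58.1, a linear model with group as the only term was fitted to each probe set (lmFit, eBayes), with two-sided moderated tests and Benjamini-Hochberg adjustment over 21187 probe sets, and adjusted p under 0.05 counted as changed. No filter was used. Fold changes are GATA2 against control. Gene lists, 24 in number, and 8 lists of cell type markers were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

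Named genes followed a rule fixed before the data were examined: Gata2, 7 fixed regulators or markers, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, without unnamed gene models, up to 3 called members of each list by adjusted p or else the 2 with the largest absolute log2 fold change, and the 2 brightest members of each cell type list. Genes named beyond that rule were chosen after their values were seen and are identified as such where they appear.

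The equal replicate numbers of both groups were checked for pairing. Across genes, deviations from the group mean correlated at 0.34, 0.29 and 0.55 between arrays of the same number, and at -0.43 to 0.13 between arrays of different number, genes not being independent replicates. The fit planned before the data were examined has no block, and a fit with the replicate number as a block is given beside it where it changes a call or moves a count by over 1.5 times. Other alternatives were a filter on dim probe sets, trended and robust variances, 3 normalisations between arrays, array weights, 1 probe set per gene, the other table, other thresholds, and each array left out in turn. Leaving out pairs of arrays was chosen after the data had been seen. A comparison by the authors was not found in the tables.

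The procedure was tested on simulated data with 200 changed genes among 21187, with 3 arrays per group. Noise was drawn independently for each gene. In the real arrays genes can move together (estimated correlation 0.85 in the interferon list), so the false-call counts below may not carry over to them. Without pair effects, the fit with group only recovered 24%, 82%, 96% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 1 false call among 152. With pair effects it recovered 8%, 72%, 94% and 100%, with 0 false among 137. The fit with the replicate number as a block recovered 0%, 62%, 88% and 96% without pair effects, with 1 false among 124, and 12%, 72%, 88% and 98% with them, with 1 false among 136.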

Results

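Gene expression was profiled on 6 single-colour Affymetrix arrays in primary mesenchymal stromal cells from the subcutaneous white adipose tissue of male C57BL/6J mice, cells that can be turned into adipocytes or osteoblasts in culture. One group of 3 arrays came from cells infected with a retrovirus carrying an empty vector (control), and the other group of 3 came from cells infected with the same vector carrying the coding sequence of mouse GATA2, a zinc finger transcription factor of haematopoietic and adipocyte precursors. Each array gave a value for 21187 probe sets, 1 per Entrez gene, and the median log2 intensity lay between 6.49 and 6.58 in every array. The comparison asks which transcripts differ when GATA2 is over-expressed in these cells. Their number, 3 against 3, limits the precision, and no source says whether the replicates were separate animals or separate cultures, so the p-values measure only the spread between these samples.

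Gata2 (Entrez 14461) was higher in all 3 GATA2 arrays. Its log2 intensity was 9.49 ± 0.21 (SD, n = 3) in control cells and 11.70 ± 0.11 (SD, n = 3) in GATA2 cells, a log2 fold change of 2.21 ± 0.12 (SE) or 4.62-fold (limma, adjusted p = 0.00094). The construct held the coding sequence only, so probes outside it can see only the cells' own transcript, and the 29 probes of this set give 1 summary value. That call was lost only when both arrays of replicate 2 were left out (adjusted p = 0.125). Of the other GATA factors and GATA-like genes, 9 were measured. Trps1, a GATA-type repressor of chondrocyte and bone development, fell by 0.95 on the log2 scale (SE 0.17, adjusted p = 0.029), and the remaining members did not pass the test (camera adjusted p = 0.492 for the list). Adjusted over the list alone, 0 were higher and 1 was lower.

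In total 901 genes passed an adjusted p of 0.05 (limma), 419 higher and 482 lower in GATA2 cells, and 256 of them differed at least 2-fold, 119 higher and 137 lower. All 901 had the 3 GATA2 arrays on one side of the 3 control arrays, which passing the test nearly requires. So did 25.3% of all probe sets, where 10% is the average for exchangeable arrays. Genes move together, so the share can lie far from 10% without a group effect, and it is no test. After median centring the split of calls was 542 higher and 411 lower. With the replicate number as a block the count was 2748 (1289 higher, 1459 lower), with 403 at least 2-fold (162 higher, 241 lower), and all 901 were among them. Without control replicate 1, 2 or 3 the count was 273, 305 or 479, and without GATA2 replicate 1, 2 or 3 it was 208, 40 or 1087. The counts of genes changed at least 2-fold were then 163, 171, 194, 98, 36 and 367. Of the 901 calls, 39 held with each of the 6 arrays left out in turn. On the first principal component, with 59.1% of the variance, control replicates 1, 2 and 3 scored -13.9, -14.3 and -39.7, and GATA2 replicates 1, 2 and 3 scored 32.2, 28.0 and 7.62. Across genes, which are not independent replicates, the group difference correlated at 0.25, 0.43 and -0.48 with the difference of replicate 1, 2 or 3 from the other replicates.

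The largest rise was that of Msln (Entrez 56047), which encodes the surface glycoprotein mesothelin. Its log2 intensity went from 5.69 ± 0.16 in control cells to 10.31 ± 0.26 in GATA2 cells (SD, n = 3 each), a 24.6-fold difference (limma, adjusted p = 7.2e-05). Elmod1, which encodes an ELMO domain protein, rose by a log2 fold change of 3.77 ± 0.13 (SE, adjusted p = 9.0e-05). The other 10 of the 12 largest rises lay between 4.95-fold and 8.11-fold. They were Ly6f, Nrep, the cardiac troponin gene Tnnt2, the small proline-rich gene Sprr2f, the semaphorin Sema3e, the keratin Krt18, the neuropeptide Y receptor gene Npy6r, the natural killer cell ligand H60b, the cardiac T-box factor Tbx20 and the pituitary hormone prolactin (Prl). All 12 passed the test with the replicate number as a block as well. Of these 12 calls, 10, 10 and 11 held without control replicate 1, 2 or 3, and 8, 6 and 12 without GATA2 replicate 1, 2 or 3.

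The largest fall was that of Abi3bp (Entrez 320712), which encodes an extracellular matrix protein. It fell from a log2 intensity of 9.89 ± 0.69 in control cells to 6.32 ± 0.77 in GATA2 cells (SD, n = 3 each), 11.9-fold lower (limma, adjusted p = 0.012). Haptoglobin (Hp) was 7.51-fold lower, the growth factor Hgf 6.42-fold lower, the retinoic acid synthesising enzyme Aldh1a2 6.28-fold lower and Lrrc17 5.46-fold lower. Complement component C4b, the water channel Aqp1, the chemokine Cxcl5, the lipopolysaccharide binding protein Lbp, Tmem176b, the transforming growth factor beta-induced matrix protein Tgfbi and pleiotrophin (Ptn) were 4.23-fold to 5.32-fold lower. Aqp1 had the smallest adjusted p of the 12 (log2 fold change -2.39 ± 0.11 SE, adjusted p = 0.00037). All 12 passed with the replicate number as a block too. Of these 12 calls, 7, 9 and 11 held without control replicate 1, 2 or 3, and 6, 3 and 12 without GATA2 replicate 1, 2 or 3.

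**Figure D1:**
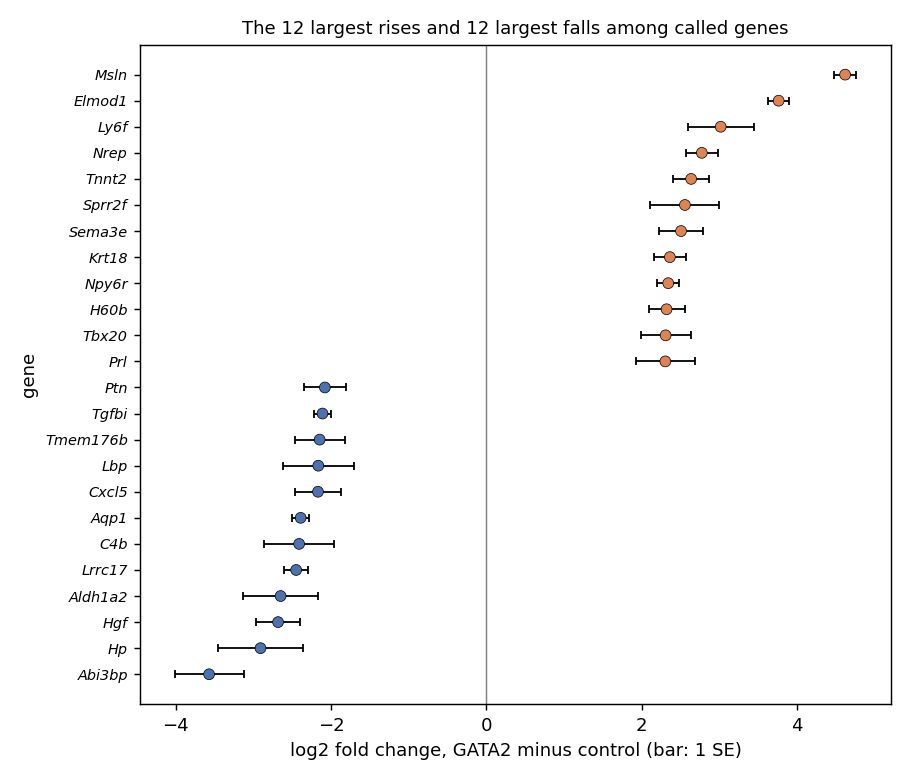
The log2 fold change (GATA2 minus control, horizontal axis) of the 12 largest rises and 12 largest falls among genes past the test, with 1 SE to each side (n = 3 arrays per group). Msln at 4.62 and Abi3bp at -3.57 form the ends.

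Among 24 gene lists fixed beforehand, 14 differed from the other genes by limma's camera test with a preset correlation of 0.01, 11 toward lower and 3 toward higher expression in GATA2 cells. With the correlation between genes estimated from the data none of the 24 passed, and the smallest adjusted p was 0.158. In the osteoblast, mesenchymal progenitor and Wnt lists the estimates were -0.00305, -0.0304 and 0.00412, below the preset 0.01. A larger correlation within these lists is therefore not why they failed in that version of the test. Fry, which asks whether the genes of a list move in 1 direction on balance, passed 3 lists, and 7 with the replicate number as a block. The 3 were the osteoblast (fry adjusted p = 0.0090), mesenchymal progenitor (0.0014) and Wnt (0.011) lists, all toward lower expression. Each of them also passed fry with the block (adjusted p = 0.037). The numbers of called members given next are over all 21187 genes unless another basis is stated. Cdh11, Procr, Gdf6, Pfkl, Shox2, Itga6, Slit3, Robo1, Ephb2, Ntn1, Sox17, Mbp and Rgs5 are named to complete small counts and were chosen after their values were seen.

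**Figure D2:**
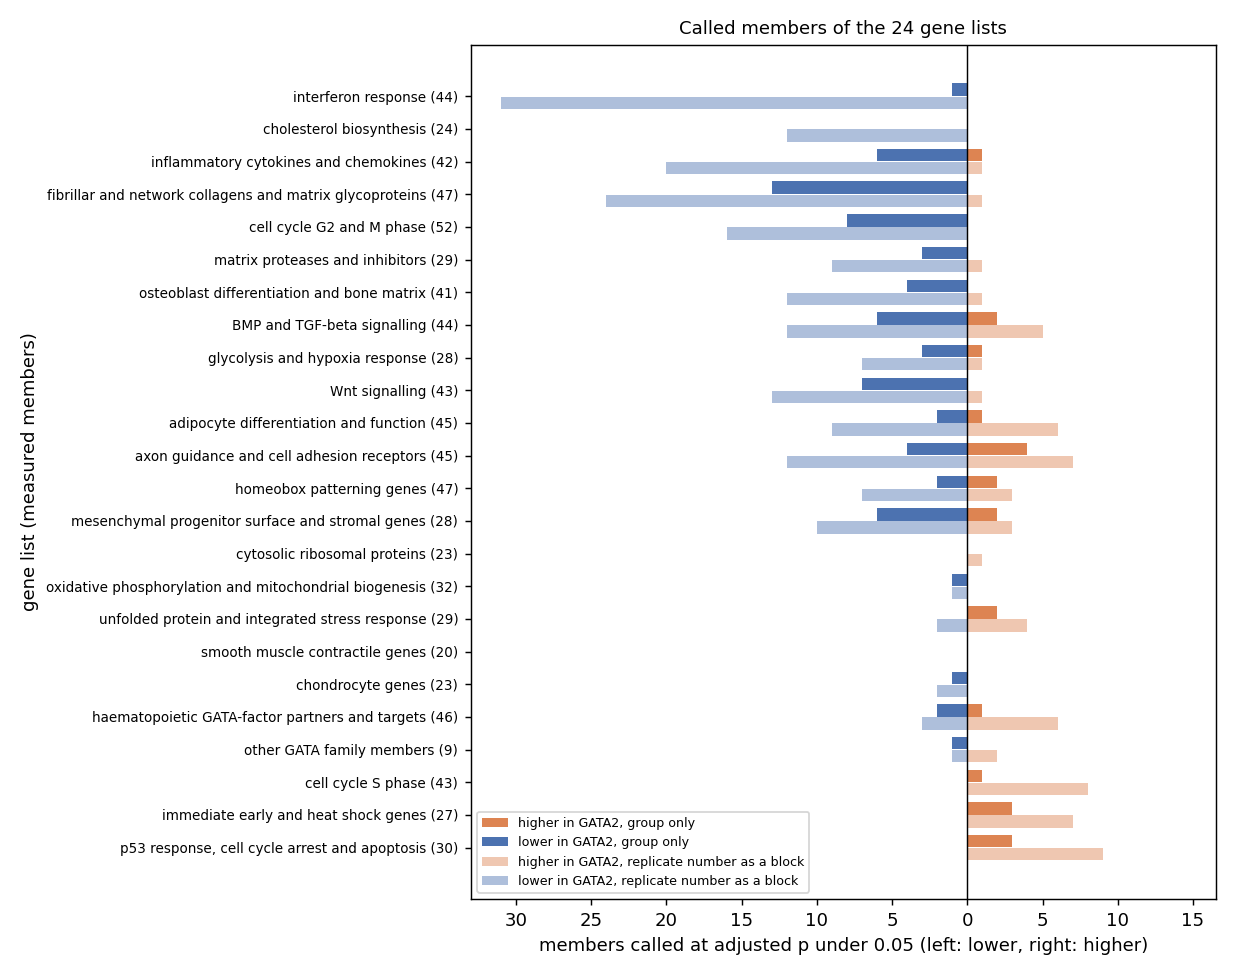
Members of the 24 gene lists that passed adjusted p under 0.05, to the left when lower and to the right when higher in GATA2 cells (number of genes, horizontal axis). Dark bars are from the fit with group only and pale bars from the fit with the replicate number as a block. The interferon list shows the widest gap, 1 against 31 lower members.

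Of 41 measured genes of osteoblast differentiation and bone matrix, 4 fell and none rose, and the list passed camera toward lower expression (adjusted p = 0.0010) but not with an estimated correlation (adjusted p = 0.158). Enpp1, which makes the mineralisation inhibitor pyrophosphate, was 3.65-fold lower (adjusted p = 0.014), the matrix proteoglycan Fmod 2.43-fold lower (adjusted p = 0.046), osteopontin (Spp1) 1.72-fold lower (adjusted p = 0.0081) and the cadherin Cdh11 lower by a log2 fold change of -0.93 ± 0.20 (SE). Of the regulators and markers of osteoblast formation, Runx2 had a log2 fold change of -0.50 ± 0.14 (SE, adjusted p = 0.104), Sp7 of 0.16 ± 0.13 (adjusted p = 0.566), and the alkaline phosphatase gene Alpl of -1.71 ± 0.40 (adjusted p = 0.061). The osteocalcin gene Bglap had a log2 fold change of 0.15 ± 0.17 (adjusted p = 0.692). When the replicate number was a block, Runx2 (adjusted p = 0.013) and Alpl (adjusted p = 0.0049) passed, and the called members of the list were 1 higher and 12 lower. There were 1 higher and 11 lower members adjusted over the list alone. Of the 4 calls, 2, 2 and 2 held without control replicate 1, 2 or 3 and 1, 0 and 3 without GATA2 replicate 1, 2 or 3.

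Of 45 measured genes of adipocyte differentiation and function, 1 rose and 2 fell: the acyl-CoA synthetase Acsl1 was higher by a log2 fold change of 0.48 ± 0.09 (SE, adjusted p = 0.030), Zfp467, a zinc finger regulator of the choice between fat and bone, was 1.84-fold lower (adjusted p = 0.029), and the early adipogenic factor Cebpb was 1.52-fold lower (adjusted p = 0.038). Pparg, the main regulator of adipocyte formation, had a log2 fold change of 0.65 ± 0.22 (SE, adjusted p = 0.154), and Cebpa one of -0.74 ± 0.17 (adjusted p = 0.063). With the replicate number as a block both passed, Pparg as higher (adjusted p = 0.012) and Cebpa as lower (adjusted p = 0.0045), and the list held 6 higher and 9 lower members. The list as a whole did not pass camera (adjusted p = 0.166, estimated correlation adjusted p = 0.617). There were 3 higher and 7 lower members adjusted over the list alone. Of the 3 calls, 1, 0 and 1 held without control replicate 1, 2 or 3 and 0, 0 and 2 without GATA2 replicate 1, 2 or 3.

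**Figure D3:**
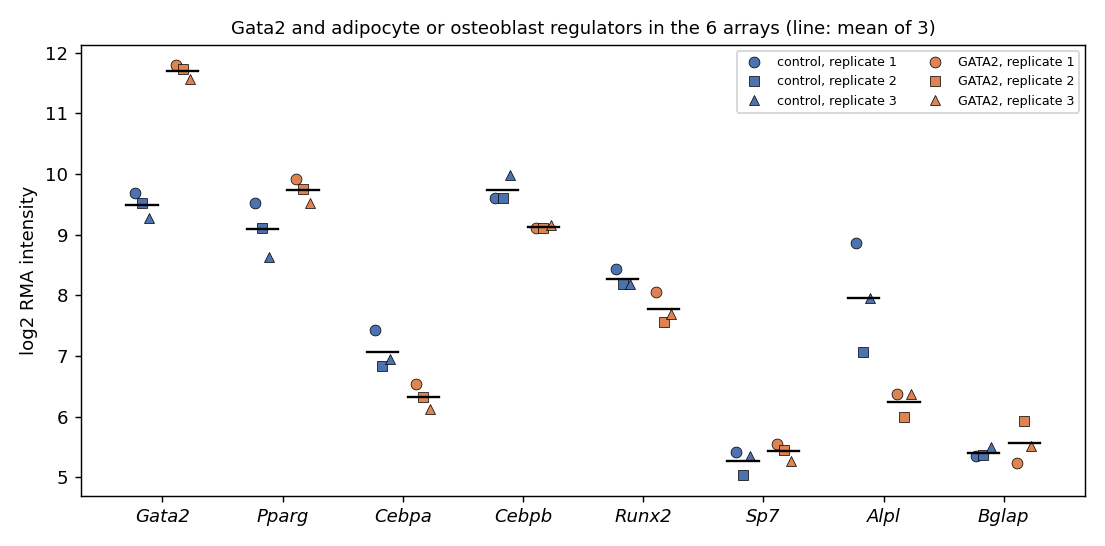
The log2 RMA intensity (vertical axis) of Gata2 and 7 regulators or markers of adipocytes and osteoblasts in each array, with the marker shape giving the replicate number and the line the mean of 3 arrays. Gata2 lies at 9.49 in control and 11.70 in GATA2 cells, and Alpl at 7.96 and 6.25.

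Of 28 measured genes that mark mesenchymal progenitors and stroma, 6 fell, 2 rose and 20 did not pass. Camera gave an adjusted p of 0.015 toward lower expression and, with an estimated correlation, an adjusted p of 0.325. The BMP antagonist Grem1 was 2.48-fold lower (adjusted p = 0.0047) and the progenitor surface marker Cd34 3.36-fold lower (adjusted p = 0.014), while the ecto-nucleotidase Nt5e (CD73), itself a stromal marker, was 2.98-fold higher (adjusted p = 0.011). The other riser was Procr, with a log2 fold change of 1.11 ± 0.22 (SE). The members adjusted over the list alone were 3 higher and 8 lower, and with the replicate number as a block 3 were higher and 10 lower. Of the 8 calls, 2, 3 and 3 held without control replicate 1, 2 or 3 and 4, 1 and 7 without GATA2 replicate 1, 2 or 3.

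In the BMP and TGF-beta list 6 of 44 measured members fell and 2 rose (camera adjusted p = 0.025, or adjusted p = 0.367 with an estimated correlation). Tgfbi was 4.32-fold lower (adjusted p = 0.00083) and the co-receptor Tgfbr3 3.13-fold lower (adjusted p = 0.023), while the ligands Tgfb2, 2.51-fold higher (adjusted p = 0.012), and Gdf6, with a log2 fold change of 0.60 ± 0.11 (SE), rose. In the Wnt list 7 of 43 members fell and none rose (camera adjusted p = 0.00032, or adjusted p = 0.158 with an estimated correlation). The agonist Rspo2 was 2.29-fold lower (adjusted p = 0.011), the secreted antagonist Frzb 2.14-fold lower (adjusted p = 0.015) and the R-spondin receptor Lgr6 2.17-fold lower (adjusted p = 0.023), so the members that fell included activators and inhibitors of the pathway. When adjusted over the list alone, 3 were higher and 8 lower in the BMP and TGF-beta list, and 0 higher and 11 lower in the Wnt list. When the replicate number was a block, the calls were 5 higher and 12 lower, and 1 higher and 13 lower. Of the 15 calls in both lists, 5, 4 and 10 held without control replicate 1, 2 or 3 and 3, 1 and 14 without GATA2 replicate 1, 2 or 3.

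Of 47 measured collagens and matrix glycoproteins, 13 fell and none rose (camera adjusted p = 4.0e-11, or adjusted p = 0.367 with an estimated correlation). The proteoglycan Vcan was 2.66-fold lower (adjusted p = 0.0068), and the collagen VI chains Col6a1 and Col6a2 were 3.13-fold and 2.84-fold lower (adjusted p = 0.012 and 0.017). Of 29 matrix proteases and inhibitors, 3 fell and none rose: the protease inhibitor Serpine2 was 2.16-fold lower, the metalloproteinase Mmp19 2.66-fold lower and tissue plasminogen activator (Plat) 3.20-fold lower. Camera gave the protease list an adjusted p of 0.0011, or adjusted p = 0.459 with an estimated correlation. Adjusted over the list alone, 1 was higher and 18 were lower among the matrix genes, and 1 higher and 7 lower among the proteases. With the replicate number as a block, 24 matrix genes were lower and 1 higher, and 9 proteases or inhibitors were lower and 1 higher. Of the 16 calls, 4, 5 and 8 held without control replicate 1, 2 or 3 and 4, 1 and 15 without GATA2 replicate 1, 2 or 3.

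Of 42 measured inflammatory cytokine and chemokine genes, 6 fell, 1 rose and 35 did not pass (camera adjusted p = 2.7e-07, or adjusted p = 0.348 with an estimated correlation). Cxcl5 was 4.49-fold lower, the interleukin 1 receptor antagonist Il1rn 2.47-fold lower (adjusted p = 0.013) and the chemokine Cx3cl1 1.96-fold lower (adjusted p = 0.011), whereas Tnfaip3, an inhibitor of NF-kappaB signalling, was 2.19-fold higher (adjusted p = 0.0089). Of 44 measured interferon response genes, Irf1 alone passed the test (1.78-fold lower, adjusted p = 0.041). The list had a median log2 fold change of -0.96, and 43 of its 44 members had a negative value. Its per-array median log2 intensity was 8.18, 8.26 and 9.51 in control replicates 1, 2 and 3 and 7.43, 7.39 and 8.15 in the GATA2 replicates. When the replicate number was a block, 31 interferon genes were lower and none higher, and 20 inflammatory genes were lower and 1 higher. Camera gave the interferon list an adjusted p of 3.1e-12, or adjusted p = 0.459 with an estimated correlation. There were 2 higher and 17 lower inflammatory genes, and no interferon gene, past the test adjusted over the list alone. Of the 8 calls in both lists, 4, 3 and 5 held without control replicate 1, 2 or 3 and 3, 0 and 6 without GATA2 replicate 1, 2 or 3.

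**Figure D4:**
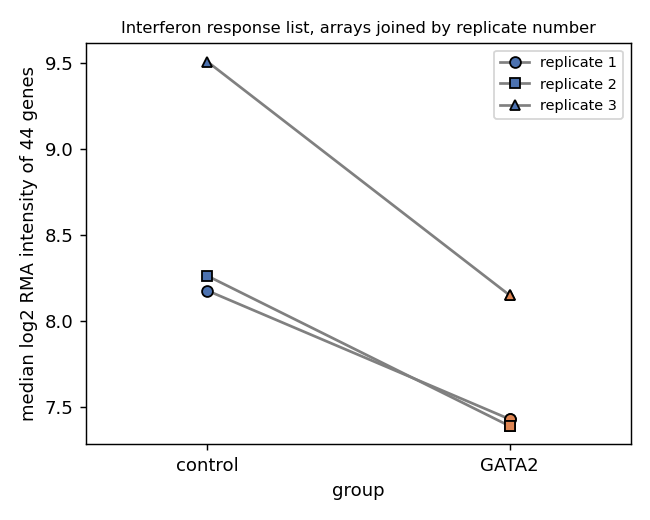
Median log2 RMA intensity of the 44 interferon response genes in each array (vertical axis) for control and GATA2 cells, with lines joining arrays of the same replicate number. Replicate 3 starts highest, at 9.51, and the line falls in each of the 3 pairs.

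Of 52 G2 and M phase genes, 8 fell and none rose, among them the kinesin Kif2c (1.68-fold lower, adjusted p = 0.017) and the mitosis-promoting phosphatases Cdc25b (1.64-fold lower, adjusted p = 0.017) and Cdc25c (1.48-fold lower, adjusted p = 0.026). Of 43 S phase genes, the cyclin gene Ccne2 rose 1.73-fold (adjusted p = 0.030) and none fell. Among 30 genes of the p53 response, arrest and apoptosis, 3 rose and none fell: the cyclin-dependent kinase inhibitors Cdkn1c (2.54-fold, adjusted p = 0.038) and Cdkn2a (1.55-fold, adjusted p = 0.049), and the stress gene Gadd45b (1.41-fold, adjusted p = 0.039). Camera gave adjusted p = 4.5e-13 for the G2 and M list, 0.011 for the S list and 3.5e-06 for the arrest list. With an estimated correlation these were adjusted p = 0.386, 0.621 and 0.348. With the replicate number as a block 16 G2 and M genes were lower, 8 S phase genes higher and 9 arrest genes higher, with none the other way. When adjusted over the list alone, 21 G2 and M genes were lower, 1 S phase gene was higher and 8 arrest genes were higher. Of the 12 calls, 0, 1 and 9 held without control replicate 1, 2 or 3 and 1, 0 and 7 without GATA2 replicate 1, 2 or 3.

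Haematopoietic partners and targets of GATA factors showed 1 rise and 2 falls among 46 measured members. The mast cell tryptase Tpsab1 was 3.59-fold higher (adjusted p = 0.031), while Cd34 and the interleukin 33 receptor Il1rl1 (3.39-fold lower, adjusted p = 0.034) fell. The list did not pass camera (adjusted p = 0.202, or adjusted p = 0.506 with an estimated correlation). Adjusted over the list alone, 2 were higher and 3 lower. When the replicate number was a block, 6 were higher and 3 lower, and 2 other GATA family members were higher and 1 lower. Of the 4 calls in the haematopoietic and GATA family lists, 1, 1 and 2 held without control replicate 1, 2 or 3 and 1, 0 and 3 without GATA2 replicate 1, 2 or 3.

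Metabolic lists differed in what passed. No gene of cholesterol biosynthesis passed the test by limma over all genes, although 23 of 24 measured members had a negative log2 fold change (median -0.55), 13 were lower adjusted over the list alone, and 12 were lower with the replicate number as a block. Pmvk, which encodes phosphomevalonate kinase, had a log2 fold change of -0.81 ± 0.18 (SE, adjusted p = 0.055, or 0.0082 with the replicate number as a block). In glycolysis and hypoxia response, with 28 measured members, the endoplasmic reticulum oxidase Ero1a rose 1.75-fold (adjusted p = 0.0081), and the mitophagy gene Bnip3 (1.58-fold), the lactate exporter Slc16a3 (2.21-fold) and the phosphofructokinase Pfkl (log2 fold change -0.56 ± 0.11 SE) fell. With the replicate number as a block 1 was higher and 7 lower, and adjusted over the list alone 1 was higher and 8 lower. In the oxidative phosphorylation list Cox7a1 alone of 32 members passed, 1.54-fold lower (adjusted p = 0.0098), and 1 was lower adjusted over the list alone. Camera gave adjusted p = 1.5e-09 for cholesterol biosynthesis, 0.011 for glycolysis and hypoxia, and 0.202 for oxidative phosphorylation. With an estimated correlation these were adjusted p = 0.459, 0.459 and 0.710. Of the 5 calls, 3, 2 and 4 held without control replicate 1, 2 or 3 and 2, 0 and 5 without GATA2 replicate 1, 2 or 3.

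Of 27 immediate early and heat shock genes, which respond to handling of cells, Zfp36 (1.61-fold), Fos (1.87-fold) and Klf6 (1.28-fold) rose and none fell (camera adjusted p = 0.0081, or adjusted p = 0.459 with an estimated correlation). Of 29 genes of the unfolded protein response, Ddit3 and Dnajb9 rose, each with a log2 fold change of 0.48, (camera adjusted p = 0.977, toward higher expression although the median log2 fold change was -0.03). Axon guidance and adhesion receptors had 4 rises, of Sema3d (2.34-fold, adjusted p = 0.0089), Sema3e (5.69-fold), Efna5 (1.83-fold) and Itga6, and 4 falls, of Slit3, Robo1, Ephb2 and Ntn1, among 45 members (camera adjusted p = 0.331). Homeobox patterning genes had 2 rises, among them that of Hoxd4 (1.37-fold), and 2 falls, of Prrx2 (2.34-fold) and Shox2, among 47 members (camera adjusted p = 0.106). Of 23 chondrocyte genes, Col10a1 fell 1.41-fold (camera adjusted p = 0.468, toward lower expression although the median log2 fold change was 0.01). None of 20 smooth muscle genes passed (camera adjusted p = 0.614), with the largest values those of Mylk (-0.21) and Synpo2 (-0.19). None of 23 measured ribosomal protein genes passed (camera adjusted p = 0.468), with the largest values those of Rpl22 (-0.37) and Rpl23 (0.35), of which Rpl23 passed as higher with the replicate number as a block (adjusted p = 0.035).

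For these 7 lists in the same order, handling genes, unfolded protein response, axon guidance, homeobox, chondrocyte, smooth muscle and ribosomal proteins, the calls with the replicate number as a block were 7, 4, 7, 3, 0, 0 and 1 higher and 0, 2, 12, 7, 2, 0 and 0 lower. Adjusted over the list alone they were 4, 3, 7, 3, 0, 0 and 0 higher and 0, 1, 12, 5, 1, 0 and 0 lower. Their 18 calls included Sema3e and Fos, and 5, 6 and 8 of the 18 held without control replicate 1, 2 or 3 and 2, 0 and 13 without GATA2 replicate 1, 2 or 3.

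Markers of other cell types were examined in 8 further lists, and none passed camera (adjusted p between 0.131 and 0.834), while by fry the mesothelial and epithelial list (adjusted p = 0.036) and the mast cell list (adjusted p = 0.038) passed. By fry with the replicate number as a block the mesothelial and epithelial list passed (adjusted p = 0.00034), the mast cell list did not (adjusted p = 0.115), and the pericyte list did (adjusted p = 0.025, against 0.115 without the block). In the mesothelial and epithelial list Msln and Krt18 rose and none fell among 19 members, while Krt19 had a log2 fold change of -0.61 ± 0.50 (SE, adjusted p = 0.574) and Krt8 one of 1.05 ± 0.64 (adjusted p = 0.431). Among 22 endothelial genes Sox17 rose (log2 fold change 1.26 ± 0.12 SE), with Emcn at 0.80 ± 0.50 and Edn1 at -0.03 ± 0.15. None of 22 macrophage and myeloid genes passed, and Cd53 (-0.94 ± 0.28, adjusted p = 0.115) and Cd68 (1.28 ± 0.29, adjusted p = 0.059), the brightest of them, had opposite signs and both passed with the replicate number as a block (adjusted p = 0.012 and 0.00056). Of 13 mast cell genes Tpsab1 rose and Il1rl1 fell, and Srgn had a log2 fold change of 0.71 ± 0.24 (adjusted p = 0.146, or 0.040 with the replicate number as a block). None of 16 lymphocyte genes passed, with Lck at -0.17 ± 0.09 and Cd3e at 0.09 ± 0.08. Of 12 pericyte genes Rgs5 fell (log2 fold change -0.94 ± 0.15 SE), with Pdgfrb at -0.26 ± 0.09 and Mcam at 0.51 ± 0.31. None of 21 skeletal muscle genes passed, with Acta1 at -0.10 ± 0.13 and Des at 0.04 ± 0.11. Of 15 Schwann and neural genes Tubb3 fell 2.48-fold (adjusted p = 0.024) and Mbp rose (log2 fold change 1.08 ± 0.14 SE), with Pmp22 at 0.26 ± 0.08. Of the 8 calls in these lists, 5, 4 and 6 held without control replicate 1, 2 or 3 and 4, 2 and 7 without GATA2 replicate 1, 2 or 3. Emcn (adjusted p = 0.45) passed with the replicate number as a block (adjusted p = 0.0019). Adjusted over the list alone, 1 endothelial, 2 mast cell, 3 mesothelial and epithelial and 1 Schwann and neural gene were higher, and 1 mast cell, 2 pericyte, 1 mesothelial and epithelial and 1 Schwann and neural gene were lower. When the replicate number was a block, in the order endothelial, macrophage, mast cell, lymphocyte, pericyte, mesothelial, skeletal muscle and neural, 2, 1, 3, 0, 0, 3, 0 and 1 were higher and 0, 3, 1, 0, 4, 0, 0 and 1 lower. Cd34, Pdgfrb, Mcam, Des, Tpsab1 and Il1rl1 each stand in more than 1 list.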

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

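Leaving out pairs of arrays was chosen after the results were seen, and the other alternatives before. Changed genes numbered 901. They were 2748 with the replicate block, 3227 with array weights (0.708, 1.72 and 0.737 for control and 0.472, 4.09 and 0.579 for GATA2 replicates 1, 2 and 3) and 86 at adjusted p under 0.01. Without both arrays of replicate 1, 2 or 3 they were 23, 4 or 1064, and with the block on pairs 2 and 3, 1 and 3, or 1 and 2 they were 2465, 1438 or 2543. The number of genes changed at least 2-fold was 256, and then 403 with the block, 407 with array weights and 597 at a log2 fold change of 0.58. Without both arrays of replicate 1, 2 or 3 they were 23, 4 or 356, and with the block on those pairs 421, 418 or 413. Changed lists, 14 in the planned test, were 0 with an estimated correlation and 3 by fry. Gata2 had an adjusted p of 0.125 and a log2 fold change of 2.21 without both arrays of replicate 2. With single arrays left out, the ranges were 40 (without GATA2 replicate 2) to 1087 (without GATA2 replicate 3) changed genes, 36 to 367 changed at least 2-fold, 12 to 16 lists and a Gata2 log2 fold change of 2.10 to 2.30. Filtering, trended variances, quantile normalisation, median centring, cyclic loess, 1 probe set per gene and the other table, whose values differ by a relative 4.95e-10 at most, gave between 837 and 953 changed genes, 219 to 262 at least 2-fold and 13 or 14 lists. Fits with arrays left out had fewer samples, and the filter tested fewer genes. Yet the count without GATA2 replicate 3 (1087) was above that with all arrays (901), so the number of samples is not the only factor. How much each accounts for was not tested.

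No gene called among those named reversed. The values that changed direction belonged to genes and lists that had not passed: Acta1 at 0.044 with array weights and 0.027 with the block on pairs 2 and 3, Bglap at -0.056, Des at -0.0028 and Edn1 at 0.035 with the block on pairs 1 and 3, Des at -0.0061 and Edn1 at 0.0011 with the block on pairs 2 and 3, and Edn1 at 0.0085 after quantile normalisation. Lists changed direction at adjusted p = 0.895 (smooth muscle, array weights), 0.903 and 0.916 (unfolded protein response, cyclic loess and trended variances), 0.848 (haematopoietic partners, filter), 0.912 (unfolded protein response, block on pairs 1 and 3), and 0.581, 0.459 and 0.459 (ribosomal, oxidative phosphorylation and smooth muscle, block on pairs 2 and 3). With arrays left out, Acta1 lay at -0.196 to 0.055, Bglap at -0.056 to 0.316, Des at -0.057 to 0.134 and Edn1 at -0.177 to 0.090, and adjusted p at 0.182 to 0.802 (ribosomal), 0.0265 to 0.493 (oxidative phosphorylation), 0.302 to 0.892 (smooth muscle) and 0.603 to 0.996 (unfolded protein response). The cause was not tested. The planned comparison with the authors' own test was not run, since no table holds one. Detection calls were not used here, so what signal over background limits is unknown.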

Other observations

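The tests of the mesothelial, gene family, interferon and added gene sets were chosen after the results were seen, except that of the genes beside the clusters, and the counts over other splits were planned. The genes named here and not in the report were chosen after their values were seen.

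A set of 30 cardiac genes, put together after the values were seen and holding Tnnt2 and Tbx20 of the 12 largest rises, had a median log2 fold change of 0.10 and was not tested for enrichment. Of its members 5 rose: Tnnt2, Tbx20, the natriuretic peptide gene Nppb (log2 fold change 2.03 ± 0.28 SE), Popdc2 (1.96 ± 0.21) and Popdc3 (1.53 ± 0.20), while the gap junction gene Gja1 fell by 0.69 on the log2 scale (SE 0.13). With the replicate number as a block 7 were higher and 2 lower. Nppa, Myh6 and Nkx2-5 had log2 fold changes of 0.02, 0.06 and 0.01. Of 16 complement and acute phase genes put together in the same way (median log2 fold change -1.37), 5 fell: C4b, Hp, Lbp, C1s1 (log2 fold change -1.81 ± 0.33 SE) and Masp1 (-0.90 ± 0.08), and 1 rose. With the block 1 was higher and 11 were lower, among them C3 (-1.62 ± 0.48, adjusted p = 0.110 without the block). Without control replicate 1, 2 or 3, 4, 4 and 5 of the 6 cardiac calls and 2, 4 and 5 of the 6 complement calls held, and without GATA2 replicate 1, 2 or 3, 2, 1 and 6 and 2, 1 and 5 held.

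Of 10 genes of steroid synthesis and response, also put together after the values were seen (median log2 fold change -0.12), Hsd3b1 rose (log2 fold change 1.91 ± 0.24 SE) and Esr1 (-0.84 ± 0.11) and Cyp1b1 (-1.62 ± 0.27) fell. With the block 1 was higher and 4 lower, and of the 3 calls 2, 3 and 3 held without control replicate 1, 2 or 3 and 2, 0 and 3 without GATA2 replicate 1, 2 or 3. The urothelial gene Upk1b (2.19 ± 0.45) and the ligand gene Wnt7a (2.11 ± 0.28) rose as well.

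Msln and Krt18 rose, and mesothelial cells in the GATA2 cultures are a possible explanation that stays open. The other 7 mesothelial markers of the fixed list had a median log2 fold change of 0.22 (SE 0.08). Of these, 4 (Upk3b, Wt1, Lrrn4 and Gpm6a) lay below the median level of all probe sets in control cells, as Msln did. Their mean log2 intensities in GATA2 cells were 5.38, 5.49, 5.20 and 4.17, and none passed the test. In the same order their log2 fold changes were 0.08, 0.25, 0.29 and 0.10 (SE 0.10, 0.12, 0.10 and 0.08), small but all positive. Without detection calls it is unknown whether their probe sets would respond, so they do not decide the question. The most abundant of the 7, Krt8 and Krt19, had values of 1.05 ± 0.64 and -0.61 ± 0.50 (SE). An effect of GATA2 over-expression itself was not tested.

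Of 23 prolactin family genes, 6 rose (Prl, Prl7b1, Prl7d1, Prl8a9, Prl8a2 and Prl7a2), and of 7 Serpinb9 genes 5 rose, with 1 and 0 of these calls kept without GATA2 replicate 2. Of the 23 prolactin members 12 lay within 2 SE of 0, all below the median level of all probe sets in control cells. Prl8a2, Prl7a2 and Prl7d1 rose from control means also below it (3.95, 4.07 and 4.38). So no rise beyond 2 SE was measured in those 12, and a low level did not keep Prl8a2, Prl7a2 and Prl7d1 flat. Without detection calls it is unknown whether the probe sets of the 12 would respond. Cross-hybridisation between the prolactin members that rose stays open, and the 12 do not decide it for the whole family. Of the Serpinb9 members 0 of 7 lay within 2 SE of 0, so there too it stays open for the whole family. For the region, 190 other genes were taken, those between the outermost members of each family on chromosome 13 and the nearest on each side. Their median log2 fold change was 0.0245 (SE 0.0125), and 0.03 (SE 0.03) in the 82 of them at or above the median level. These values argue against a change of that whole stretch. They do not speak to a change confined to the genes closest to the members, which was not tested. The families were noticed among the 30 largest called rises. Without the 2 prolactin members and 1 Serpinb9 member there, 4 of 21 and 4 of 6 members were called higher (one-sided Fisher exact p = 0.000679 and 2.172e-06 against other probe sets). These p-values are no independent test, since the families were chosen for rises in the same arrays and their members are not independent of each other. A response of both families remains a hypothesis, which this count does not separate from cross-hybridisation.

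The median difference of the interferon response genes was -0.76, -0.72 and -1.15 in the 3 pairs. Replicate 3 alone is argued against by a mean of -0.74 over pairs 1 and 2. A shift of all genes alike is argued against as the cause, since the list fell against the other genes. In the 3 pairs 42, 41 and 44 of its 44 members were lower, while the median of all probe sets differed by at most 0.0394. Normalisation to near-equal medians fixes that last value, so whether all genes shifted before it is unknown. Chance differences between cultures in genes that move together could account for it and stay open, since the exact sign-flip permutation p is 0.25, the smallest that 3 pairs can give.

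The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 901 changed genes, 256 changed at least 2-fold and 14 lists, and the highest of the other splits gave 0, 0 and 11, with 1 of 10 splits as large each time. The replicate numbers appear to pair the samples, judged only by the correlated deviations in these arrays. The 3 other splits that part all such pairs gave at most 9 lists without the block. With the block they gave 0 genes, against 2748. Every other split mixes control and GATA2 arrays, so any group difference widens the spread within its groups. Counts of 0 in those splits are therefore no separate evidence for the 901 or 2748 calls.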
